A study of Mus musculus with 16 samples.

How the data were processed

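Whole-genome bisulfite sequencing and RNA sequencing of hippocampus from male C57Bl6N mice aged 6 months were analysed, with 2 libraries of each kind for WT, Neil1KO, Neil2KO and DKO (16 libraries). Groups and replicate numbers come from the sample labels, which do not say whether replicates are separate animals and name no litter or batch. Comparisons, tests, thresholds and the rule for naming genes were fixed before the data were examined, except where stated here or in the closing section.

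Each bisulfite file holds 1 value per CpG cytosine, the percent of reads that stayed unconverted, which the authors made with Bismark and methylKit on GRCm38/mm10, per the submitters' processing notes. They give no coverage or read count per site, and versions and site filters are not given in the sources used here. The gene table holds read counts that the authors normalised between libraries, a signal made with HISAT and DESeq2 on GRCm38/mm10, per the submitters' processing notes. The normalised counts are not whole numbers and could not be turned back into reads, since of values up to 20 times the smallest of a library only 10.1 to 20.4% lay within 0.1 of a whole multiple of it. Transcript tables give FPKM per transcript and mean coverage per base, per the file headers. They list 117579 transcripts. Of these 11094 (9.44%) carry no reference name, and 4246 genes share a locus with at least 1 of them. The program that made the transcript tables, the counting step, its strand handling and all tool versions are not given in the sources used here. No reference genome was used here.

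For expression, the deposited normalised counts of 21971 genes were taken as log2(value + 1), and 17758 genes with a mean of at least 10 over the 8 RNA libraries were tested. A linear model with 4 genotype means was fitted with limma (empirical Bayes moderation with a trend), and each knockout was compared with WT, DKO with each single knockout, and DKO with the sum of the single effects. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Gene lists, 37 in all and covering DNA repair and methylation, cell types, neighbouring tissues, activity, metabolism, stress and synaptic function, were tested with camera at a preset correlation of 0.01 and adjusted over lists and the 3 comparisons with WT. The list of genes encoded by mitochondrial DNA had no tested gene. Locus totals, chosen after the data were seen, sum the aligned bases (coverage times length) of all transcripts of a locus, unnamed ones included, as a share of each library's total and as log2(value + 0.02) with a mean of at least 0.2.

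For methylation, sites listed in all 8 DNA libraries (15403735) gave mean levels, compared by exact permutation. Levels were averaged in 1000 bp tiles and in promoters (1000 bp on either side of the start of the most expressed transcript) with at least 3 shared sites. The planned test on methylated and unmethylated reads was not possible because the files used here hold only percent values, so limma was fitted to region means with a trend. Tiles were called at an adjusted p under 0.05 and a difference of at least 10 points, promoters at the same p and at least 5 points. A site counted as lost when at 50% or more in both WT libraries and at 10% or less in a knockout library. Stretches are 1 Mb bins with at least 10 lost sites, joined across up to 6 Mb, a definition made after the data were seen. Promoter differences and log2 fold changes were related by Spearman's rho with 100000 permutations, adjusted over 3 relations.

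Named genes follow a fixed rule. In each comparison with WT these are Neil1 and Neil2, up to 10 called genes with the largest change in each direction whose 2 knockout libraries lie beyond both WT libraries, and up to 4 members with the smallest p of each list that passed or held a called gene. For DKO against the single knockouts and the sum of their effects it is up to 5 in each direction. For methylation it is up to 5 tiles and 5 promoters in each direction, plus genes called in both promoter and expression. Not every gene the rule allows is printed, and 2 of the genes it named are not reported here.

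Depth per methylation level is unknown. The DNA libraries listed 24935858 to 28753375 sites, and levels of 1 kb tiles correlated at 0.913 to 0.926 between libraries. The RNA libraries held 5.19 to 6.07 gigabases of aligned sequence, and 1161 to 1593 genes were listed at 0 per library. On simulated data with the real spread, Neil1KO against WT, 27% of planted 2-fold and 63% of planted 4-fold expression changes were called, with 7 false calls, as were 49% of tiles moved by 20 points and 99% moved by 40 points (8 false calls), and 43 and 91% of promoters moved by 10 and 20 points (10 false calls).

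Alternatives were other pseudocounts, no filter on low values, other scaling, gene sums of FPKM (log2(FPKM + 0.1), mean of at least 0.5), a replicate block, fits of 2 genotypes only, each library left out in turn, other tile and promoter sizes, stricter thresholds, and removal of 10 Mb on either side of Neil1 and Neil2. Added after the data were seen were locus totals, the logit scale, centring of each library, at least 10 sites per region, removal of the stretches of lost sites (of a genotype or of all), an estimated correlation over locus totals, and base excision repair and the relation over called genes without Neil1 and Neil2. Where 1 library was left out, the remaining one was assumed to vary like the other genotypes. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8).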

Results

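The hippocampus of 6-month-old male C57Bl6N mice was profiled by genome-wide bisulfite sequencing and by RNA sequencing in 4 genotypes: wild type (WT), Neil1-/- (Neil1KO), Neil2-/- (Neil2KO) and mice lacking both genes (DKO). NEIL1 and NEIL2 are DNA glycosylases that start base excision repair by removing oxidised bases. The design asks how cytosine methylation in the hippocampus of the deficient mice compares with WT and how methylation relates to gene expression. Each genotype had 2 DNA libraries and 2 RNA libraries, 16 in all. Every mean ± SD below is over the 2 libraries of a genotype unless another n is given. The sources do not state whether the libraries of a genotype came from separate animals. The p-values therefore measure only the spread between these libraries, which may be technical. Levels given under other observations argue against repeats of the same DNA in Neil2KO and DKO, and do not bear on the other libraries. The DNA libraries listed between 24935858 and 28753375 CpG sites with a mean methylation level of 72.1 to 75.1%. The files give no read counts per site, so the depth behind each level is unknown. Bisulfite treatment leaves 5-methylcytosine and 5-hydroxymethylcytosine alike, so each level is the sum of both. Between RNA libraries, replicates of a genotype correlated at 0.961 to 0.970 across genes (log2 scale). Expression is given as normalised read count, and fold changes are on the log2(value + 1) scale.

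Transcripts of the targeted genes followed the genotype labels. Neil2 (chromosome 14, 63182445 to 63193525; all coordinates are GRCm38/mm10) had normalised read counts of 57.3 and 76.2 in the WT libraries and 84.3 and 78.2 in the Neil1KO libraries. It was listed at 0 in all 4 Neil2KO and DKO libraries (limma adjusted p = 0.009 and 0.0157 against WT, Benjamini-Hochberg). That call was lost without either Neil1KO library in Neil2KO (adjusted p up to 0.0712) and without either Neil1KO library or WT replicate 2 in DKO (up to 0.103), while Neil2 stayed at 0. Neil1 (chromosome 9, 57142788 to 57148038) read 209 and 212 in WT and 211 and 172 in Neil2KO, against 61.3 and 71.3 in Neil1KO and 38.7 and 65.9 in DKO. The decrease reached log2 fold change -1.66 (SE 0.286) in Neil1KO and -2.04 (SE 0.286) in DKO. It passed the adjusted threshold in neither (limma adjusted p = 0.133 and 0.18). Over the named Neil1 transcripts the mean FPKM was 1.90 ± 0.0423 in WT, 0.607 ± 0.0748 in Neil1KO and 0.471 ± 0.190 in DKO. A transcript without a reference name, with 8 exons on the minus strand of chromosome 9 (57142803 to 57148589), had an FPKM of 0.0288 and 0.0338 in WT and 0 and 0.000833 in Neil2KO, but 2.45 and 2.43 in Neil1KO and 2.12 and 1.81 in DKO. Counted with that transcript, the Neil1 locus total had a log2 fold change of 0.46 (adjusted p = 0.21) in Neil1KO and 0.21 (adjusted p = 0.904) in DKO. The decrease of named Neil1 transcripts was not a loss of all RNA from the locus.

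**Figure D1:**
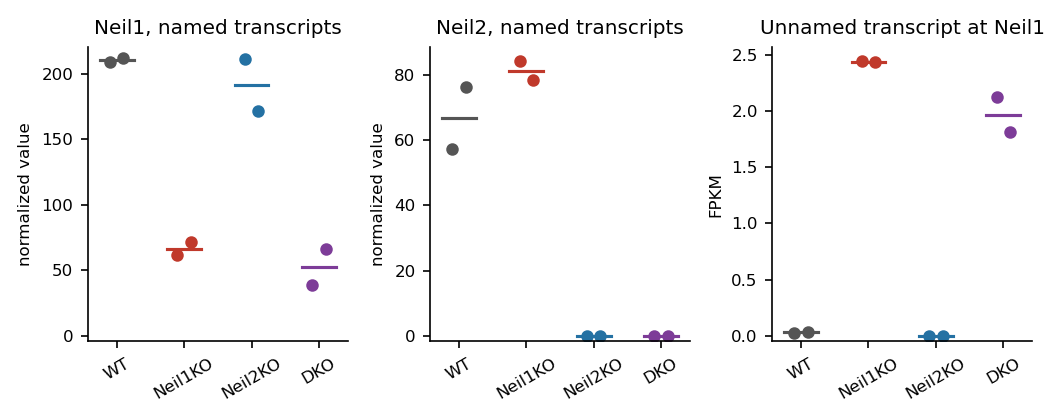
Deposited expression of Neil1 and Neil2 in each of the 8 RNA libraries, with points for single libraries and genotypes along the x axis. Neil2 is listed at 0 in the 4 Neil2KO and DKO libraries, and the unnamed Neil1 transcript rises from a mean FPKM of 0.0313 in WT to 2.44 in Neil1KO.

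In the Neil1KO hippocampus 52 of 17758 tested genes differed from WT, 24 higher and 28 lower (limma, Benjamini-Hochberg adjusted p under 0.05). The strongest decreases included Tmod2, which caps the pointed ends of neuronal actin filaments and fell from 40427 ± 765 to 1039 ± 260.2 (log2 fold change -5.30, SE 0.174, adjusted p = 0.001). Tln2, which links integrins to actin, fell from 8658 ± 801 to 494 ± 156 (-4.16, adjusted p = 0.00418). Gng2, a G protein gamma subunit, read 19782 ± 1850.5 in WT and 372 ± 199 in Neil1KO (-5.84, adjusted p = 0.00578). Znrf3, a ubiquitin ligase that removes Wnt receptors, and A830011K09Rik were listed at 0 in both Neil1KO libraries and read 219 and 244 and 100.5 and 128 in WT (adjusted p = 0.0015 and 0.00301). Ndufs7, a core subunit of mitochondrial complex I, rose from 674 ± 1.89 to 2928 ± 209 (log2 fold change 2.12, SE 0.0835, adjusted p = 0.0015).

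A stretch of chromosome 4 held the largest increases that were also present in both other deficient genotypes. Gm13304 (chromosome 4, 42114787 to 42115917) read 1.52 ± 0.708 in WT, 127 ± 3.30 in Neil1KO, 196 ± 60.5 in Neil2KO and 128 ± 0.728 in DKO (Neil1KO adjusted p = 0.00418 with limma). Its neighbours Gm21075 (41865242 to 41887262; 5.32, adjusted p = 0.00227 in Neil1KO), Gm29801 (4.21, adjusted p = 0.0103), Gm29804 (6.11, adjusted p = 0.024) and LOC101056144 (3.42, adjusted p = 0.039) were higher too. LOC101056144 did not pass in DKO (3.33, adjusted p = 0.0778). The comparisons of all knockouts use the same WT libraries, so they are not independent repeats. A difference of the WT libraries alone would give the same pattern and was not tested. Whether reads of these gene models can be told apart was not tested here. Nme3, a nucleoside diphosphate kinase on chromosome 17, read 38.4 ± 9.83 in WT, 407 ± 65.1 in Neil1KO, 407 ± 64.95 in Neil2KO and 30.1 ± 12.7 in DKO (Neil1KO against WT log2 fold change 3.38, SE 0.352, adjusted p = 0.0421). 9330159F19Rik fell from 3931 ± 44.4 to 487 ± 68.8 (-3.02, adjusted p = 0.00418). Kcnq1ot1, the imprinted long noncoding RNA of the Kcnq1 domain, fell from 1126 ± 3.15 to 503 ± 22.9 (-1.16, adjusted p = 0.0444). Htr3a, a subunit of the serotonin-gated channel of interneurons, lies on chromosome 9 (48899213 to 48911099) and fell from 671 ± 119 to 219.9 ± 13.95 (-1.60, adjusted p = 0.0455), with 282 ± 25.8 in DKO. Gm40518, on chromosome 9 as well, was listed at 0 in both Neil1KO libraries and read 69.8 and 146 in WT (adjusted p = 0.0246). Without any 1 of the 8 libraries the calls of Kcnq1ot1 (-1.21 to -1.12, adjusted p 0.0643 to 0.156), Htr3a (-1.78 to -1.42, adjusted p 0.0637 to 0.156) and Gm40518 (adjusted p 0.0519 to 0.0808) were lost with the direction kept. Gm29801 lost its call without Neil1KO replicate 1 (adjusted p = 0.0544). Nme3 lost its call without any WT, Neil1KO or Neil2KO library (3.13 to 3.64, adjusted p up to 0.132). Gm29804 lost it without any Neil1KO, Neil2KO or DKO library (up to 0.0742), and LOC101056144 lost it without any WT, Neil1KO or DKO library (up to 0.128).

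Many of the called genes lay in loci where the transcript tables also list unnamed transcripts, and their totals over named and unnamed transcripts did not pass. The locus total had a log2 fold change of -0.14 for Tmod2 (adjusted p = 0.45), -0.25 for Tln2 (0.287), -0.13 for Gng2 (0.747), 0.26 for Znrf3 (0.446), -0.39 for A830011K09Rik (0.465) and 0.12 for Ndufs7 (0.683, all limma). Apba2 (2.06 in the gene table and 0.19 over the locus) and Appbp2 (-5.72 and -0.038) lost the call in the same way. So did Guf1 (6.71 and 0.11), Gm42256 (listed at 0 in Neil1KO) and Gm14403 (listed at 0 in WT). The locus adjusted p of these 5 genes lay between 0.212 and 0.873. The chromosome 4 group, Nme3, 9330159F19Rik, Kcnq1ot1, Htr3a and Gm40518 kept theirs over the locus total. Its log2 fold change was 3.87 for Gm21075, 3.41 for Nme3, -2.86 for 9330159F19Rik, -1.15 for Kcnq1ot1 and -1.58 for Htr3a. Locus totals called 47 genes, 19 of them also called in the gene table. An unadjusted p under 0.05 was seen for 2362 genes against 888 by chance. Of the 52 genes 16 stayed called without any 1 library, 27 genes were called without either Neil2KO library and 34 without either DKO library. With only the WT and Neil1KO libraries in the fit, which leaves 4 libraries to estimate the spread, 0 genes were called. The division by direction rested on single libraries, with 46 higher and 19 lower without WT replicate 1, 56 higher and 18 lower without WT replicate 2, 9 higher and 45 lower without Neil1KO replicate 1 and 10 higher and 57 lower without Neil1KO replicate 2. Gene sums of FPKM divided the calls as 31 higher and 21 lower, against 24 and 28 here. The strand handling of the authors' counting is not stated, so reads of overlapping or antisense genes cannot be told apart.

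**Figure D2:**
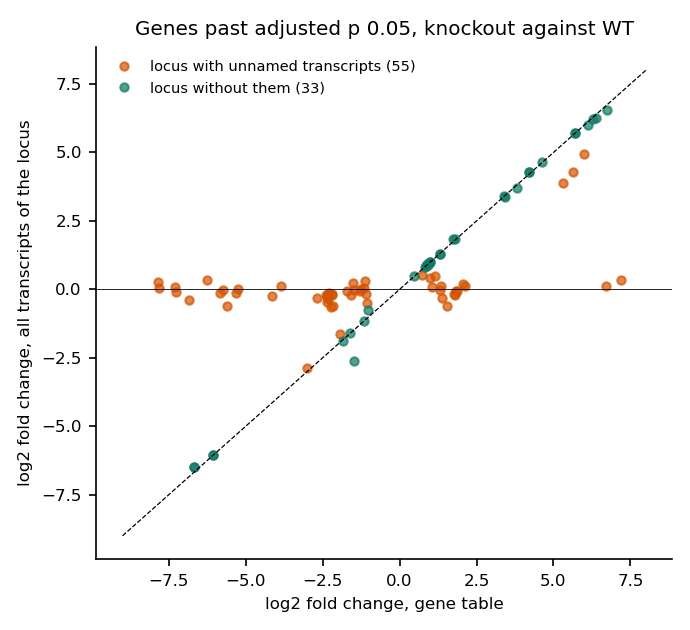
Log2 fold change of called genes against WT in the deposited gene table (one axis) and in the total over named and unnamed transcripts of the same locus (the other axis), with one point per gene and comparison. Of 88 gene and comparison pairs, 55 lie in loci with unnamed transcripts, and the median ratio of locus to table fold change is 0.0572 there. It is 0.997 in the other loci, largely by construction, since their totals hold only named transcripts.

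The list calls in Neil1KO, and all those below, held with a preset correlation between genes and not with the estimated one. Of 25 measured nuclear genes of oxidative phosphorylation 22 had positive fold changes (median 0.22; camera adjusted p = 4.58e-08; adjusted p = 0.922 with an estimated correlation). Among them were Ndufb5 of complex I (2929 ± 138 to 4218 ± 63.9, 0.53, adjusted p = 0.106) and Cox5a of cytochrome c oxidase (3942 ± 20.5 to 5142 ± 33.5, 0.38, adjusted p = 0.137). None passed alone among all genes and 11 did when adjusted over the list alone. Of 25 cytosolic ribosomal protein genes 21 were positive (median 0.31; adjusted p = 4.29e-06; adjusted p = 0.922 with an estimated correlation). Rps2 was called (2986 ± 477 to 7381 ± 168, 1.31, adjusted p = 0.0421), with 11 passing when adjusted over the list alone. The Rps2 call was lost over its locus total (-0.030) and without any library except WT replicate 2 (adjusted p up to 0.144). Of 25 immediate early genes of neuronal activity 22 were negative (median -0.30; adjusted p = 0.00405; adjusted p = 0.922 with an estimated correlation). Dusp1 read 789.8 ± 135 in WT and 555 ± 57.1 in Neil1KO, with none of the list passing when adjusted over the list alone. Of 12 markers of oligodendrocyte precursors 11 were negative (median -0.24; adjusted p = 0.0044; adjusted p = 0.922 with an estimated correlation). Among them were Cspg4 (-0.67), which encodes the NG2 proteoglycan, and Vcan (-0.40). Of 13 astrocyte markers 11 were negative (median -0.16; adjusted p = 0.0485; adjusted p = 0.922 with an estimated correlation). The glutamate transporters Slc1a2 and Slc1a3 stood at -0.65 and -0.33. In all, 1 gene of each of these 2 marker lists passed when adjusted over the list alone. Other tissue markers in Neil1KO did not pass in the gene table, with 8 of 9 blood and 9 of 10 ependymal markers positive and 15 of 16 choroid plexus markers negative (medians 1, 0.35 and -0.80; adjusted p = 0.109, 0.12 and 0.388). Over locus totals the blood markers did (adjusted p = 0.00936; adjusted p = 0.9 with an estimated correlation). Without WT replicate 1 the immediate early genes (adjusted p = 0.352) and the astrocyte markers (0.209) no longer passed. The astrocyte markers also failed without Neil1KO replicate 2 (0.194), DKO replicate 1 (0.061) or DKO replicate 2 (0.0653).

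Of the base excision repair genes other than Neil1 and Neil2, Apex1 in Neil1KO was the 1 called in a comparison with WT. Apex1, the main apurinic endonuclease, was higher (793 ± 17.6 to 1562 ± 91.8, 0.98, adjusted p = 0.044). Its locus total was not (0.43, adjusted p = 0.149) and neither was Apex1 without any 1 library (adjusted p 0.0788 to 0.159). The list did not pass in Neil1KO (11 of 25 positive, camera adjusted p = 0.618), Neil2KO (0.714) or DKO (0.109), where 2, 2 and 5 genes passed when adjusted over the list alone. Neil1 and Neil2 belong to it. The 23 genes without them did not pass either (10, 14 and 9 positive, camera adjusted p = 0.693, 0.853 and 0.559), and 1, 1 and 3 of them passed when adjusted over the list alone. In Neil2KO the median of the whole list was 0.0098 while its mean (-0.23) and the direction of the test were negative. Polb, the repair polymerase, read 1556 ± 401 in WT and 743 ± 43.9 in DKO (-1.04, adjusted p = 0.442). Imprinted genes (6 of 28 passing when adjusted over the list alone, camera adjusted p = 0.618) and enzymes and readers of DNA methylation (2 of 24, adjusted p = 0.384) did not pass as groups in Neil1KO. Of 36 lists with tested genes 23 passed in no comparison (adjusted p 0.109 to 0.991, medians -0.58 to 0.35). Among them were GABA receptors, synaptic vesicle genes, adult neurogenesis, interferon response, p53 response and CA1 pyramidal cells. Over locus totals 6 of the 23 did pass, with 0 doing so at an estimated correlation (adjusted p = 0.9 or above with an estimated correlation). These were glutamate receptors (median -0.16; adjusted p = 0.00914), postsynaptic scaffold genes (-0.13; 0.00516) and potassium and calcium channels (-0.19; 0.000675) in Neil1KO, markers of dentate granule cells in Neil2KO (0.11; 0.0159), and markers of CA2 and CA3 pyramidal cells (-0.13; 0.0182) and oligodendrocytes (-0.16; 0.00343) in DKO. Median, mean and test differed in sign in 22 list tests, none of them among the 14 that passed.

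In the Neil2KO hippocampus 21 genes differed from WT, 11 higher and 10 lower (limma). Mcu, the pore of the mitochondrial calcium uniporter, fell from 1992 ± 25.1 to 519 ± 10.2 (-1.94, adjusted p = 0.00359). Vopp1 fell from 3474 ± 187 to 982 ± 137 (-1.83, adjusted p = 0.00773). Both fell also over their locus totals (-1.62 and -1.89). Phf2, a histone lysine demethylase, fell from 3635 ± 208 to 811 ± 43.5 (-2.16, adjusted p = 0.00243), with a locus total at -0.62 (adjusted p = 0.0376). Tmem254b (483 ± 26.8 to 1199 ± 24.5, 1.31, adjusted p = 0.0163) and Tmem254c (1.31, adjusted p = 0.0158) rose, and Tmem254b read 952 ± 14.3 in Neil1KO. Both lost the call without any Neil1KO or Neil2KO library (adjusted p up to 0.0712 for Tmem254b and 0.0712 for Tmem254c). The chromosome 4 group was higher here too, with Gm21075 at 5.99, adjusted p = 0.00243, Gm13304 at 6.29, adjusted p = 0.00359, Gm29801 at 4.62, adjusted p = 0.00794, Gm29804 at 6.73, adjusted p = 0.0164 and LOC101056144 at 3.81, adjusted p = 0.0328 on the log2 scale. Gm29804 lost its call without either Neil1KO or DKO library or Neil2KO replicate 2 (adjusted p up to 0.078), and LOC101056144 without any library but Neil2KO replicate 1 (up to 0.113). Clcn6, an endosomal chloride transporter, Atpaf1, an assembly factor of mitochondrial ATP synthase, and Stam, an endosomal sorting adaptor, fell in the gene table (-2.35, -2.34 and -1.49; adjusted p = 0.00359, 0.00359 and 0.00359). Over the locus they did not pass (-0.26, -0.35 and -0.011; adjusted p = 0.795, 0.867 and 0.993). Rsl1 (listed at 0 in Neil2KO), Lacc1, Gng2, Ndufs7, Apba2 and Zranb1 likewise had locus totals that did not pass, at log2 fold changes of 0.086, -0.099, -0.61, -0.19, -0.059 and -0.61. Locus totals called 36 genes, 12 shared with the 21. Apba2 lost its gene table call without any knockout library (adjusted p up to 0.0933) and Zranb1 without any WT, Neil2KO or DKO library (up to 0.125). The number of called genes was 70 without WT replicate 1 (53 higher and 17 lower), 75 without WT replicate 2 (58 higher and 17 lower), 56 without Neil2KO replicate 1 (13 higher and 43 lower) and 40 without Neil2KO replicate 2 (7 higher and 33 lower). With only the WT and Neil2KO libraries in the fit 1 gene was called.

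In Neil2KO 3 lists were called at the preset correlation and none at the estimated one. Markers of thalamic neurons were positive for 12 of 14 genes (median 0.45; camera adjusted p = 0.00405; adjusted p = 0.922 with an estimated correlation). Tcf7l2 stood at 1631 and 359.7 in the Neil2KO libraries against 301 ± 32.4 in WT and Prkcd at 3308 and 1377 against 1227 ± 30.6. Replicate 1 carried this difference, since without it the median was -0.0097 (adjusted p = 0.735), and the list also failed without WT replicate 1 (0.377). Endothelial and pericyte markers were positive for 13 of 14 genes in Neil2KO (median 0.23; adjusted p = 0.00254; adjusted p = 0.922 with an estimated correlation). Among them were Cdh5, the endothelial cadherin (877 ± 66.6 to 1098 ± 13.8), and Pecam1 (1172 ± 126 to 1484 ± 43.1). The list failed without WT replicate 1 (0.0604) or Neil2KO replicate 1 (0.0785). Markers of neighbouring tissue leaned the same way without passing, with 13 of 14 meningeal fibroblast, 15 of 16 choroid plexus and 9 of 10 ependymal markers positive (medians 0.32, 0.55 and 0.28; adjusted p = 0.199, 0.588 and 0.376). The list of the circadian clock and glucocorticoid response was positive for 18 of 24 genes (median 0.27; adjusted p = 0.0466; adjusted p = 0.922 with an estimated correlation), Plin4 standing at 287 and 197 in WT and 425 and 1137 in Neil2KO. It failed without WT replicate 1 (0.255), Neil2KO replicate 2 (0.113), Neil1KO replicate 1 (0.0592), Neil1KO replicate 2 (0.0713) or DKO replicate 2 (0.0501). None of these members passed alone or when adjusted over the list alone.

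In the DKO hippocampus 15 genes differed from WT, 8 higher and 7 lower (limma). Pcyox1, a prenylcysteine oxidase, rose from 2175 ± 16.3 to 7558 ± 632 (log2 fold change 1.79, SE 0.112, adjusted p = 0.0141; locus total 1.85). It read 7323 ± 535 in Neil1KO and 1631 ± 177 in Neil2KO. Tm7sf3, also called higher in Neil1KO (0.85) and Neil2KO (0.93), rose from 1678 ± 43.7 to 2961 ± 70.8 in DKO (0.82, adjusted p = 0.0495). Gm40518 was listed at 0 in both libraries, as in Neil1KO (adjusted p = 0.0463). The chromosome 4 genes Gm21075 (5.63, adjusted p = 0.00813), Gm13304 (5.71, adjusted p = 0.0135), Gm29801 (4.22, adjusted p = 0.0192) and Gm29804 (6.38, adjusted p = 0.0348) were higher. Rnf214 (-2.39, adjusted p = 0.0141), the coenzyme Q biosynthesis gene Coq2 (-2.33, adjusted p = 0.0157), Lacc1 (listed at 0 in DKO) and the exoribonuclease gene Eri3 (-1.10, adjusted p = 0.0477) fell in the gene table. Their locus totals did not pass, at -0.22, -0.18, 0.066 and -0.18. Neither did those of Ndufs7 (1.76 in the table, -0.18 over the locus) and Apba2 (1.82 and -0.056). Only Gm21075 and Ndufs7 of the 15 stayed called without any 1 of the 8 libraries. Without either Neil1KO library the calls of Gm13304 (adjusted p up to 0.0588), Gm29801 (0.103, also without DKO replicate 2), Pcyox1 (0.0592) and Lacc1 (0.0727) were lost. Rnf214 lost its call without either Neil2KO library (0.053) and Coq2 without any single-knockout library (0.0738). Without any knockout library the losses were Gm29804 (0.103) and Apba2 (0.106), without any library of WT or a single knockout Eri3 (0.135), and without any library Tm7sf3 (0.0807 to 0.152) and Gm40518 (0.0585 to 0.106). The number of called genes was 5 without either Neil1KO library, 85 and 55 without DKO replicates 1 (25 higher and 60 lower) and 2 (9 higher and 46 lower), and 51 and 50 without WT replicates 1 (42 higher and 9 lower) and 2 (45 higher and 5 lower). The division by direction thus depended on the library left out. The number was 5, with 5 higher and 0 lower, with the chromosome stretches of lost sites described below left out and 0 with only the WT and DKO libraries in the fit.

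Markers of neighbouring tissue separated the DKO libraries. All 16 choroid plexus markers were positive (median 1.73; camera adjusted p = 0.00437; adjusted p = 0.922 with an estimated correlation), and DKO replicate 2 carried the difference. Tmem72 read 14.3 and 1441 in DKO replicates 1 and 2 against 26.5 and 7.79 in WT. Kl read 1868 and 9801 against 2341 and 1769.6, and the prolactin receptor gene Prlr 277 and 3259 against 282 and 295. Without DKO replicate 2 the list was lower than in WT (median -0.60, adjusted p = 0.0353), and without WT replicate 2 it did not pass (0.311). All 14 meningeal fibroblast markers were positive (median 0.59; adjusted p = 0.0051; adjusted p = 0.922 with an estimated correlation), Igf2 standing at 1872 and 4944 in WT and 4672 and 8088 in DKO. They were not past the threshold without WT replicate 1 (median -0.023, adjusted p = 0.789) or DKO replicate 2 (0.105). All 9 measured blood markers were negative (median -1.45; adjusted p = 0.000133; adjusted p = 0.922 with an estimated correlation), among them the globin genes Hbb-bt (1523 ± 92.8 to 566 ± 324) and Hba-a2 (3228 ± 235 to 1331 ± 903). The size of their median rested on the DKO library kept, at -0.794 without DKO replicate 1 and -2.11 without DKO replicate 2. Of 14 microglial markers 11 were negative (median -0.28; adjusted p = 0.00586; adjusted p = 0.922 with an estimated correlation), with Tyrobp at 452 ± 60.8 in WT and 335 ± 5.33 in DKO. They did not pass without WT replicate 1 (0.458) or DKO replicate 2 (0.174). Of 25 immediate early genes 22 were positive in DKO (median 0.36; adjusted p = 0.000133; adjusted p = 0.922 with an estimated correlation). Dusp1 stood at 789.8 ± 135 in WT and 1268 ± 129 in DKO, and Fos at 595 and 156 in the WT and 891 and 642 in the DKO libraries. The list failed without WT replicate 2 (0.525) or DKO replicate 1 (0.119). Of 20 heat shock and unfolded protein genes 16 were negative (median -0.28; adjusted p = 0.0359; adjusted p = 0.922 with an estimated correlation), with Hspa8 at 91541 ± 17247 in WT and 57697 ± 5261 in DKO. Their median was 0.12 without WT replicate 1 (adjusted p = 0.422), while the adjusted p was 0.0832 without DKO replicate 1 and 0.105 without DKO replicate 2. No member of these 6 lists passed alone or when adjusted over the list alone.

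**Figure D3:**
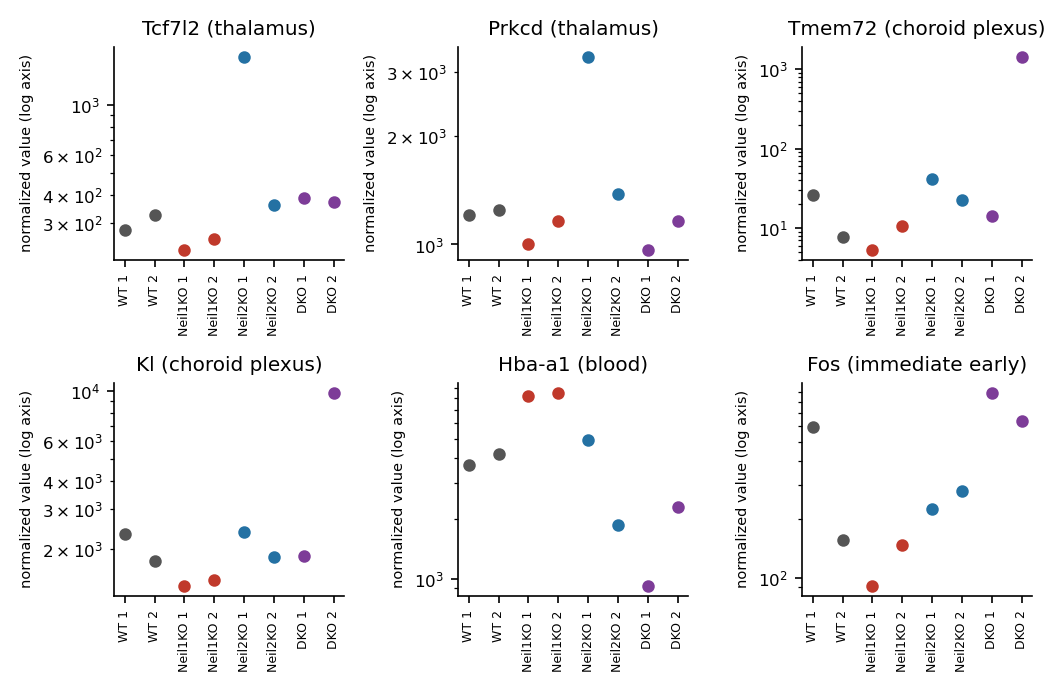
Normalised read counts (log scale) of marker genes named in the text in the 8 RNA libraries, with one point per library. DKO replicate 2 stands apart in the choroid plexus markers (Tmem72 1441 against 14.3 in DKO replicate 1), and Neil2KO replicate 1 in the thalamic marker Tcf7l2 (1631 against 359.7 in replicate 2).

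Loss of both genes was also set against loss of each alone. Against Neil1KO, 28 genes differed in DKO, 17 higher and 11 lower (limma). Tmod2, low in the Neil1KO gene counts, read 38944 ± 4198 in DKO (5.25, adjusted p = 0.00107). Neil2 (adjusted p = 0.00962) and Lacc1 (adjusted p = 0.00709) were listed at 0 in DKO. Nme3 (-3.77, adjusted p = 0.0353) and Gm27177 (-3.70, adjusted p = 0.0288) were lower. Against Neil2KO, 17 genes differed, 11 higher and 6 lower. Among them were Rsl1 (listed at 0 in Neil2KO and 194 and 215 in DKO, adjusted p = 0.000528) and Phf2 (2.31, adjusted p = 0.0025). Others were Tnni3k, a kinase gene listed at 0 in Neil2KO (23.8 and 29.0 in DKO, adjusted p = 0.0471), and Zbtb16, a zinc finger transcription factor (-2.31, adjusted p = 0.0471). The departure of the DKO from the sum of the single effects was past the threshold for 28 genes, 20 above the sum and 8 below. Nme3, called higher in Neil1KO, as high in Neil2KO without passing (adjusted p = 0.0559) and not higher in DKO, lay -7.15 from the sum (adjusted p = 0.0113), Gm21075 -5.68 (0.00721) and Gng2 10.54 (0.00388) on the log2 scale. Gm21075 was raised alike in each knockout (5.32 in Neil1KO, 5.99 in Neil2KO and 5.63 in DKO). Its departure from the sum thus rests on the WT libraries, which stood apart from every knockout. Over locus totals Neil2 (-6.15 against Neil1KO), Nme3 (-7.14 from the sum), Gm21075 (-4.51), Gm27177 (-4.13), Phf2 (0.71) and Tnni3k (4.63) kept their calls. Tmod2 (0.089), Lacc1 (0.031), Rsl1 (0.067), Zbtb16 (0.20) and Gng2 (-0.089) lost theirs.

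Of the genes called in these 3 comparisons, 9 of 28, 9 of 17 and 13 of 28 stayed called without any 1 library. Neil2 lost its call against Neil1KO without Neil1KO replicate 1 (limma adjusted p = 0.062). Nme3 lost it against both single knockouts without any library but DKO replicate 1 (up to 0.0994 and 0.142) and its departure from the sum without Neil2KO replicate 2 (0.0545). Tnni3k lost it without any library (0.0657 to 0.151), Gm27177 without any WT or single-knockout library (up to 0.0946), and Zbtb16 without any library but DKO replicate 1 (up to 0.129). Called genes against Neil1KO numbered 115 and 58 without DKO replicates 1 (48 higher and 67 lower) and 2 (16 higher and 42 lower) and 78 without Neil1KO replicate 2 (64 higher and 14 lower), gene sums of FPKM called 34 higher and 72 lower, and the fit of these 2 genotypes alone called 13. Against Neil2KO they numbered 91 and 50 without DKO replicates 1 (28 higher and 63 lower) and 2 (11 higher and 39 lower), 49 and 33 without Neil2KO replicates 1 (42 higher and 7 lower) and 2 (27 higher and 6 lower), and 6 in the fit of these 2 genotypes alone. Departures from the sum numbered 53 and 57 without WT replicates 1 (21 higher and 32 lower) and 2 (20 higher and 37 lower), 46 without Neil1KO replicate 2 (38 higher and 8 lower), 57 without Neil2KO replicate 1 (45 higher and 12 lower) and 49 without DKO replicate 1 (19 higher and 30 lower).

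Average CpG methylation of the hippocampus was alike in the 4 genotypes. Over 15403735 sites listed in all 8 DNA libraries the level was 75.6 ± 1.48% in WT, 75.7 ± 0.874% in Neil1KO, 76.3 ± 0.0390% in Neil2KO and 75.7 ± 0.0727% in DKO (SD, n = 2 libraries). None of the differences exceeded the spread between the WT libraries (exact two-sided permutation p = 1 for each of the 3 knockouts, where 2 libraries against 2 cannot go below 0.333). The 6 knockout libraries against the 2 WT libraries gave p = 0.643 (exact permutation, smallest possible 0.0357). Without WT replicate 1 the differences were 1.09, 1.77 and 1.16 points for Neil1KO, Neil2KO and DKO, and without WT replicate 2 they were -0.997, -0.318 and -0.936, so the sign rested on which WT library was kept. Without Neil1KO replicate 2 the Neil1KO difference was -0.569, against 0.667 without replicate 1. Promoters averaged 46.3 ± 0.900% in WT and 46.3, 46.8 and 46.4% in Neil1KO, Neil2KO and DKO. Gene bodies averaged 76.8 ± 1.499% in WT and 76.7, 77.5 and 76.8%, and intergenic sites 76.9 ± 1.51% and 77.1, 77.7 and 77.1%. The X chromosome, where only 32025 sites were shared, averaged 78.7 ± 1.37% and 78.9, 79.4 and 78.8%. Promoters of imprinted genes, with 1305 shared sites, averaged 59.0 ± 3.42% and 58.9, 58.9 and 58.6%. The smallest exact permutation p of a single knockout over these features was 0.667, in tiles of at least 50 listed sites (79.2 ± 0.223% in Neil2KO, 78.7 ± 0.889% in WT).

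The knockouts read low instead at single sites packed into long stretches, with most of the sites on the chromosomes that carry the targeted genes. In Neil1KO, 6439 sites on chromosome 9 between 32 and 78 Mb, a stretch that contains Neil1 at 57.1 Mb, were at 50% or more in both WT libraries and at 10% or less in both Neil1KO libraries, with 219 more between 95 and 99 Mb. In Neil2KO, 2866 such sites lay on chromosome 14 between 45 and 80 Mb, around Neil2 at 63.2 Mb. Of these 2847 lay between 54 and 80 Mb, and from 45 to 54 Mb sites were lost mainly in replicate 2. DKO had stretches around both genes, with 3934 sites on chromosome 9 (39 to 65 Mb) and 2878 on chromosome 14 (54 to 80 Mb), and further ones on chromosome 1 (81 to 106 Mb, 1806 sites) and chromosome 11 (113 to 118 Mb, 395 sites). These sites are called lost, though a low value does not show whether the cytosine is unmethylated or the site is absent from the knockout's sequence. Of the lost sites of a genotype 98.9% (Neil1KO), 97.4% (Neil2KO) and 99.4% (DKO) lay in its stretches (6734, 2941 and 9083 sites in all), while the opposite change was seen at 189, 141 and 159 sites in the genome. Of the lost DKO sites inside the chromosome 9 stretch 97.2% were also lost in Neil1KO (3824 of 3934), and of those on chromosome 14 96.5% were also lost in Neil2KO (2778 of 2878). The single libraries had lost 6633 and 6560 sites in the large Neil1KO stretch, but 2942 and 5776 on chromosome 14 in Neil2KO replicates 1 and 2. On chromosome 5 (31 Mb from 77 Mb on) 2699 sites were lost in DKO replicate 1 and 16 in replicate 2.

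**Figure D4:**
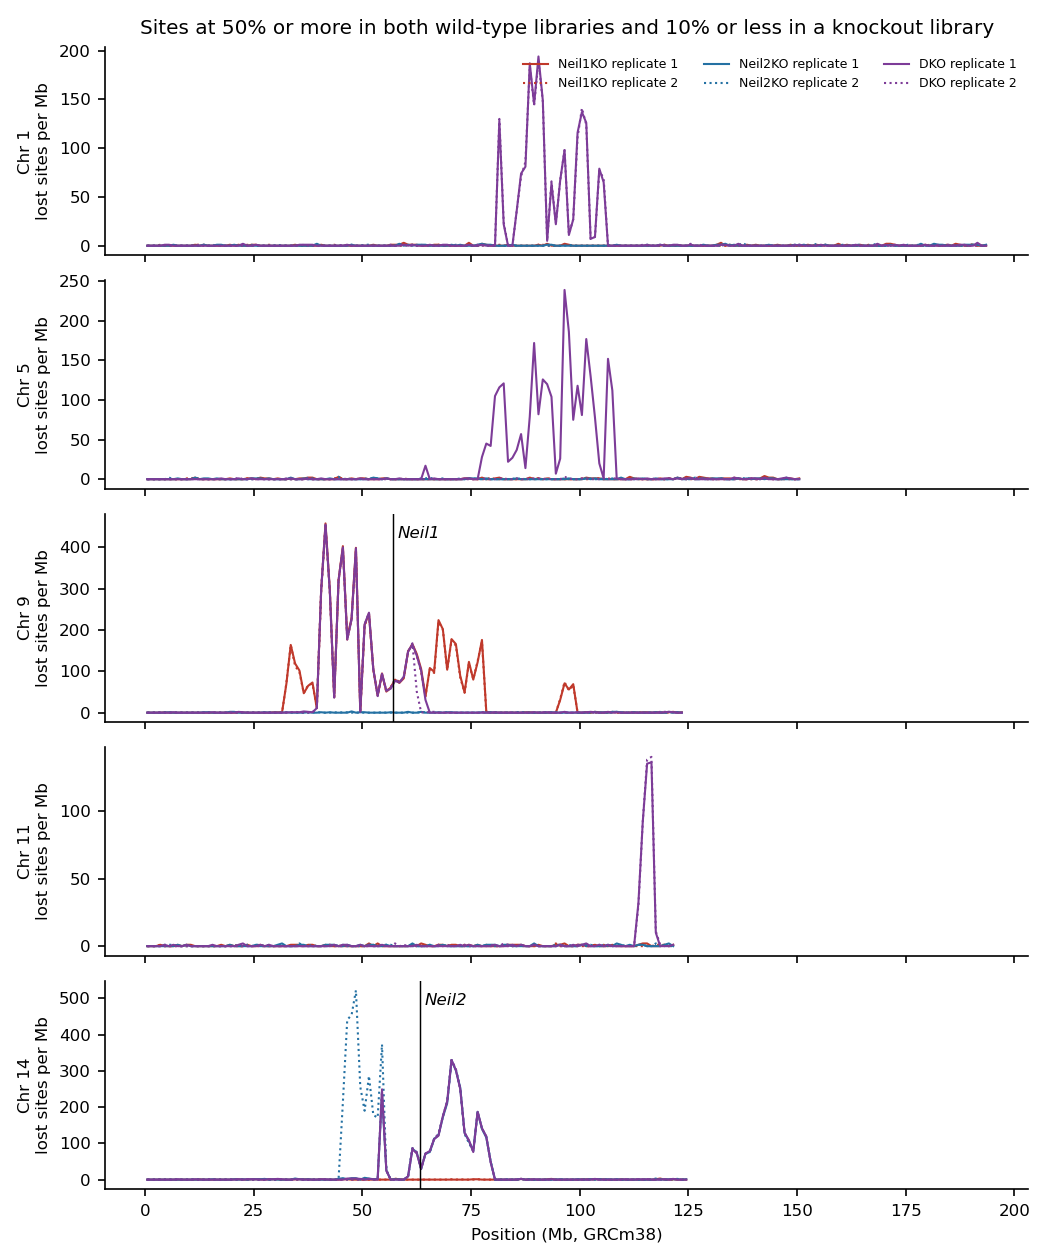
Number of lost CpG sites per 1 Mb bin along the chromosomes with stretches of lost sites (x axis in Mb), for the libraries of Neil1KO, Neil2KO and DKO. Lost sites (50% or more in both WT libraries and 10% or less in the library shown) crowd around Neil1 on chromosome 9 and Neil2 on chromosome 14, and DKO adds chromosomes 1, 5 and 11.

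In 1 kb tiles the largest gains of methylation in Neil1KO lay outside these stretches. A tile inside Camk2b, the beta subunit of calcium/calmodulin-dependent kinase (chromosome 11, 6006001 to 6007000, 7 sites), stood at 4.19 ± 0.226% in WT, 80.7 ± 5.29% in Neil1KO, 1.10 ± 1.55% in Neil2KO and 71.6 ± 7.61% in DKO (Neil1KO difference 76.5 points, SE 4.78, adjusted p = 4.34e-12 with limma). The next tile rose from 10.6 ± 5.89% to 72.6 ± 4.65% (difference 62.0 points, SE 3.04, adjusted p = 6.03e-15). Between genes, 4896 bp from the lipid kinase gene Pik3c3, a tile of 15 sites (chromosome 18, 30267001 to 30268000) rose from 10.1 ± 1.55% to 79.8 ± 1.19% and 82.7 ± 3.53% in DKO, with 2.77 ± 2.73% in Neil2KO (difference 69.7 points, SE 3.45, adjusted p = 6.03e-15). A tile at the start of LOC108169013 (chromosome 4, 134160001 to 134161000) stood at 0% and 19.7% in the WT libraries and 84.7% and 73.6% in Neil1KO (difference 69.3 points, SE 4.09, adjusted p = 1.12e-12). The largest losses lay in the chromosome 9 stretch. Here, 11230 bp from Gm32335 the level went from 89.0 ± 1.05% to 0 in both Neil1KO and both DKO libraries. Near Gm40533 it went from 87.8 ± 0.365% to 1.70 ± 0.320% in Neil1KO but was 85.6 ± 2.88% in DKO, and in the body of Acsbg1, an acyl-CoA synthetase gene, it went from 92.2 ± 1.32% to 15.8 ± 3.54% (adjusted p = 1.03e-09, 2.22e-11 and 1.66e-10 for these 3 tiles). Near Gm35940 and AI593442 the levels were 91.9 ± 1.28% and 80.5 ± 6.89% in WT and 5.13% and 3.03% and 0% and 0% in the Neil1KO libraries. Of 1685300 tiles, 1440 were called (97 higher, 1343 lower, at least 10 points). Of the lower ones 1269 lay inside the stretches, as follows in part from drawing these around sites low in the same libraries. Within 10 Mb of Neil1, a window fixed before the data were seen, lay 411 of the 1343 (30.6%) and 0.943% of the tested tiles. The count was 627 and 760 without WT replicates 1 and 2, 742 and 890 without Neil1KO replicates 1 and 2. It was 149 on the logit scale, where LOC108169013 lost its call, 444 in tiles of at least 10 sites, and 68 (35 higher, 33 lower) with the stretches left out.

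In Neil2KO 649 tiles were called, 76 higher and 573 lower, and 550 of the lower ones lay in the chromosome 14 stretch (limma). Near 2410012E07Rik (chromosome 14, 70881001 to 70882000) the level went from 86.5 ± 3.73% in WT to 0 in both Neil2KO libraries. Near 4933402J15Rik it went from 71.2 ± 0.293% to 0 in both, near Gm34757 from 96.9 ± 0.814% to 27.2 ± 0.786%, in Gm35218 from 91.9 ± 4.58% to 16.9 ± 0.820%. In the body of Sucla2, a subunit of succinate-CoA ligase, it went from 91.5 ± 1.05% to 24.4 ± 0.918% (difference -67.2 points, SE 6.07, adjusted p = 9.46e-08). The largest gain lay 6349 bp from Klhl33 (chromosome 14, 50904001 to 50905000, 14 sites), where the level rose from 26.1 ± 1.73% to 58.0% and 81.1% in the Neil2KO libraries and was 55.5 ± 1.03% in DKO (difference 43.4 points, SE 4.44, adjusted p = 1.14e-06). The start of Gm29936 on chromosome 16 stood at 52.6 ± 3.70% in WT, 70.2 ± 2.99% in Neil1KO, 86.4 ± 1.34% in Neil2KO and 78.2 ± 2.48% in DKO (difference 33.7 points, SE 3.91, adjusted p = 1.42e-05). Both of these gains lost the call on the logit scale. The tiles at Gm32288 (36.2 points), Gm13470 (35.1) and Gm31135 (32.4) were higher in Neil2KO by less certain margins. Their mean levels were 64.6, 89.3 and 63.7% in Neil1KO, against 64.9, 81.7 and 75.2% in Neil2KO and 28.7, 46.5 and 42.8% in WT. The calls at Gm32288 (33.5 to 38.9 points) and Gm31135 (29.4 to 35.4) were lost without any WT or Neil2KO library and that at Gm13470 (31.4 to 38.9) without either WT library or Neil2KO replicate 2. The count of tiles was 241 and 246 without WT replicates 1 and 2, 205 without Neil2KO replicate 2, 36 on the logit scale, 127 in tiles of at least 10 sites and 20 (13 higher, 7 lower) with the stretches left out.

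In DKO 2217 tiles were called, 118 higher and 2099 lower, 1974 of the lower ones inside its stretches (limma). Tiles near Gm35940, Gm32335 and AI593442 on chromosome 9 and 2410012E07Rik on chromosome 14 were as low as in the respective single knockout, by -90.2, -89.0, -80.5 and -85.8 points. A tile in Rnf152 (chromosome 1, 105334001 to 105335000) stood at 79.3 ± 4.15% in WT, 84.4 ± 4.56% in Neil1KO, 81.1 ± 0.329% in Neil2KO and 0 in both DKO libraries (difference -79.3 points, SE 6.81, adjusted p = 9.08e-09). The gains were those of Neil1KO at Pik3c3 (difference 72.6 points, SE 3.45, adjusted p = 2.45e-15) and Camk2b (difference 67.4 points, SE 4.78, adjusted p = 1.68e-10), and a tile 936 bp from Gm39972 on chromosome 2 (42.5 ± 3.93% in WT, 97.0 ± 1.61% in DKO and 94.2 ± 4.06% in Neil1KO, difference 54.6 points, SE 5.25, adjusted p = 8.29e-08). Outside the stretches of all genotypes 153 tiles were called in Neil1KO, 83 higher and 70 lower. With the tiles of the stretches left out of the fit and its adjustment, 65 of them were still called (34 higher, 31 lower). In 80 of the 153 all 4 Neil1KO and DKO libraries lay beyond the 4 WT and Neil2KO libraries, 36 higher and 44 lower. The count of DKO tiles was 970 without DKO replicate 1, 1394 without DKO replicate 2, 926 and 1187 without WT replicates 1 and 2, 313 on the logit scale, 631 in tiles of at least 10 sites and 79 (37 higher, 42 lower) with the stretches left out.

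**Figure D5:**
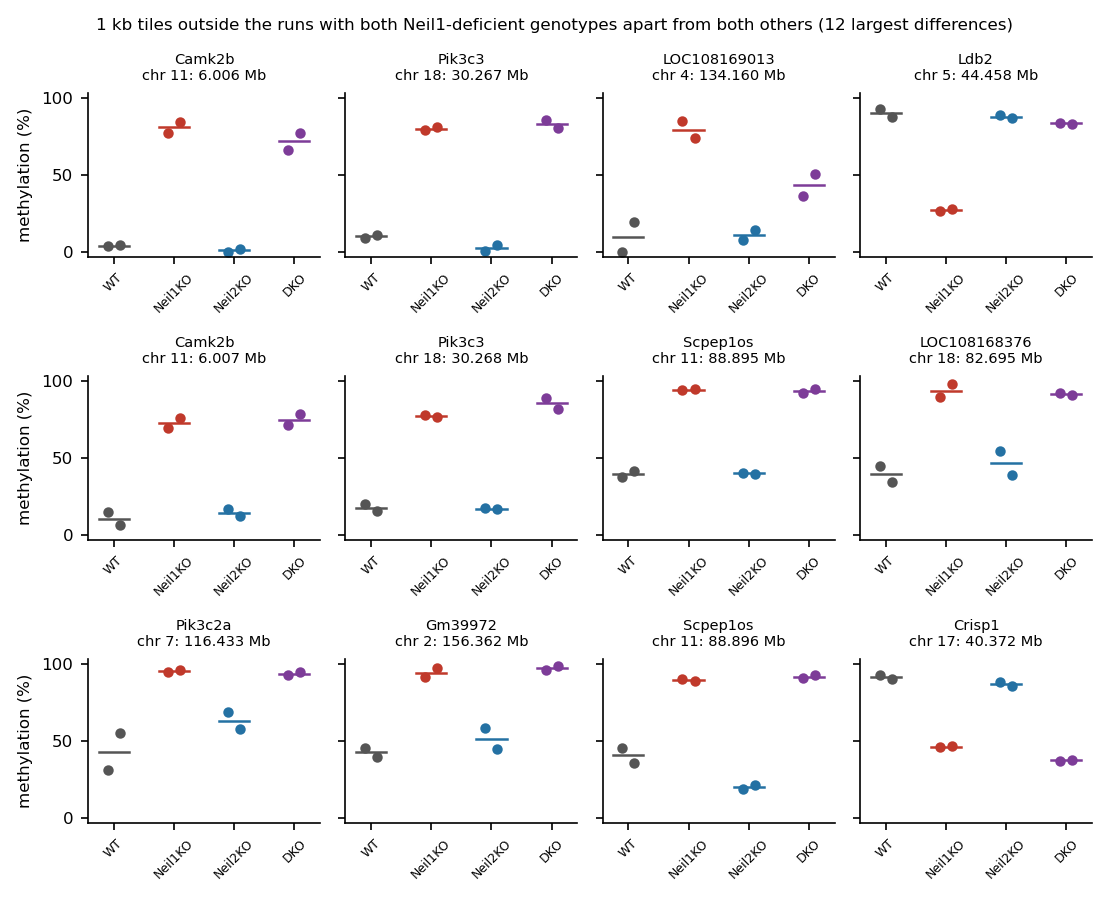
Methylation level (percent) in each of the 8 DNA libraries for the 12 tiles outside the stretches with the largest differences among those where both Neil1-deficient genotypes lie apart from WT and Neil2KO. In the Camk2b tile the 4 Neil1-deficient libraries sit between 66.2 and 84.4% and the 4 others between 0 and 4.35%. In the Ldb2 tile Neil1KO stood at 26.7 and 27.5%, but DKO at 83.6 and 83.1%, close to Neil2KO (88.4 and 87.0%).

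Promoters, taken as 1000 bp on either side of the start of the most expressed transcript, differed at 12 of 32649 genes in Neil1KO (5 higher, 7 lower, at least 5 points). The promoter of Gm40812, which overlaps the Camk2b gene (chromosome 11, 6005610 to 6007610), stood at 4.44 ± 1.76% in WT, 71.0 ± 2.48% in Neil1KO and 70.2 ± 11.3% in DKO (difference 66.6 points, SE 3.99, adjusted p = 3.4e-05 with limma), and that of LOC108169013 at 0% and 19.7% in the WT and 84.7% and 73.6% in the Neil1KO libraries (69.3 points, adjusted p = 0.000458). The promoters of Cxcl1, a neutrophil-attracting chemokine (26.8 ± 5.53% to 54.1 ± 0.254%), of the complement inhibitor gene Cd59a (52.8 ± 0.884% to 68.9 ± 3.76%) and of Gm40843 (76.0 ± 1.40% to 85.8 ± 1.58%) gained methylation. Inside the chromosome 9 stretch, promoters of Arcn1, the delta subunit of the COPI vesicle coat (55.8 ± 3.99% to 18.9 ± 2.08%, difference -36.9 points, SE 3.08, adjusted p = 0.000458), LOC108167706 (-37.8 points), Gm35177 (-26.4) and 4930502A04Rik (-23.8) fell, as did that of 3110070M22Rik on chromosome 13 (-27.1). Gm40812, LOC108169013, LOC108167706, Arcn1 and Gm35177 kept the call without any 1 library. Cxcl1 (23.4 to 31.2 points) lost it without WT replicate 2 or either Neil1KO library, and Cd59a (13.4 to 18.8) without any WT or Neil2KO library or Neil1KO replicate 1. Gm40843 (8.70 to 10.9) and 4930502A04Rik (-26.4 to -21.3) lost it without any WT or Neil1KO library, and 3110070M22Rik (-28.6 to -25.7) without either WT library or Neil1KO replicate 1. Of the 12 promoters 6 lay inside the stretches, and 6 were called with these left out. After each library was centred on its median, 36 promoters were called, 10 higher and 26 lower. The count was 5 without Neil1KO replicate 1, 7 and 6 without WT replicates 1 and 2, 2 with 500 bp on either side, 3 on the logit scale and 1 with only WT and Neil1KO in the fit.

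The Neil2 promoter itself was more methylated where Neil2 was targeted. Its level (chromosome 14, 63192525 to 63194525, 31 sites) was 56.5 ± 3.23% in WT, 57.4 ± 3.15% in Neil1KO, 79.0 ± 1.85% in Neil2KO (difference 22.5 points, SE 2.26, adjusted p = 0.0117 with limma) and 72.1 ± 1.02% in DKO (difference 15.7 points, SE 2.26, adjusted p = 0.0305). The other 3 called promoters were lower in Neil2KO: Gm9199 (-18.3 points), Pebp4 (-18.1) and Arhgap33os (-13.6). In DKO 30 promoters were called, 10 higher and 20 lower. Higher ones included Gm40812 (65.8 points), the kinase gene Stk25 on chromosome 1 (13.0 ± 2.18% to 40.8 ± 1.18%, difference 27.8 points, SE 2.37, adjusted p = 0.000644), the fucosyltransferase gene Fut4 (42.5 ± 1.06% to 58.6 ± 1.63%), Gm41190 (16.4), and Cxcl1 (19.4). Lower ones included Arcn1 (-36.1), LOC108167706 (-33.7), 2410012E07Rik (-36.6), 4930481A15Rik (33.4 ± 7.39% to 4.32 ± 0.476%) and 3110070M22Rik (-27.2). Gm40812, Stk25 and Arcn1 kept the DKO call without any 1 library. The Neil2 promoter lost its call in both genotypes without any WT, Neil2KO or DKO library (20.2 to 24.8 points in Neil2KO, 13.4 to 18.0 in DKO), as did 4930481A15Rik in DKO (-34.3 to -23.8). Without any 1 of the 8 libraries the calls were lost at Gm9199 (-18.7 to -17.9), Pebp4 (-18.8 to -17.4) and Arhgap33os (-15.7 to -11.5) in Neil2KO and at Cxcl1 (15.5 to 23.4), Gm41190 (13.2 to 19.5), Fut4 (14.95 to 17.3) and 2410012E07Rik (-41.4 to -31.9) in DKO. LOC108167706 (-34.3 to -33.2) lost the DKO call without WT replicate 1 and 3110070M22Rik (-28.7 to -25.6) without any WT or DKO library. Inside the stretches lay 3 of the 4 called promoters in Neil2KO (Neil2, Gm9199 and Pebp4) and 22 of the 30 in DKO, among them Neil2, Stk25, Gm41190, Cxcl1, Arcn1, LOC108167706 and 2410012E07Rik. With the stretches left out 0 and 4 promoters were called. In all 0 or 1 promoter was called in Neil2KO without any 1 library, and in DKO 15 without either Neil1KO library, 10 without either Neil2KO library, 4 and 5 without DKO replicates 1 and 2, and 3 and 6 without WT replicates 1 and 2. Centring each library called 28 promoters in Neil2KO and 68 in DKO, the logit scale 0 and 5, and the fits of 2 genotypes alone 0 and 7.

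Promoter methylation and expression were compared across 16703 genes in each knockout, 3 relations in all. Neil2 was the gene called in both measures, its promoter more methylated and its transcript listed at 0 in Neil2KO and DKO. It is the targeted gene, so its call in both measures is no evidence of a relation between them. No other gene was called in both, in any of the 3 comparisons. Among the 16703 genes 5, 1 and 14 promoters and 39, 12 and 9 genes were called in Neil1KO, Neil2KO and DKO. Chance alone predicts an overlap of 0.0117, 0.000718 and 0.00754 genes. With so few calls, the lack of further overlap cannot show whether the 2 measures are related. Spearman's rho between the promoter difference and the log2 fold change was -0.0215 in Neil1KO (permutation p = 0.006, adjusted 0.018), -0.00458 in Neil2KO (permutation p = 0.553, adjusted 0.731) and -0.00267 in DKO (permutation p = 0.731, adjusted 0.731). The test was two-sided with 100000 permutations over genes, which are not independent replicates. The Neil1KO relation did not pass without WT replicate 2 (rho -0.00793, permutation p = 0.303) or Neil1KO replicate 1 (-0.0146, permutation p = 0.0545), and it was -0.000141 over called genes alone. It was -0.0244 with 500 bp on either side of the start (permutation p = 0.00450), -0.0356 with the methylation of gene bodies (permutation p = 0.000500) and -0.0333 without WT replicate 1 (permutation p = 0.000999), p-values of alternatives being unadjusted. Called genes in this relation are those of the 16703 called in promoter methylation, in expression or in both. Over the 12 of Neil2KO rho was -0.594 (permutation p = 0.0485), and over the 11 other than Neil2 it was -0.491 (permutation p = 0.132).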

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

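All tests of explanations in this part were chosen after the results were seen. For 28 genes the effect of losing both NEIL genes differed from the sum of the single effects by a test of the difference itself (limma interaction). Of these, 10 were also called over locus totals, where 20 genes passed. WT alone standing apart gives such a departure too, as at Gm21075. A signal also appeared in transcripts that the gene comparisons do not use: the unnamed transcript at Neil1 had a mean FPKM of 2.44 in Neil1KO and 1.97 in DKO, against 0.0313 in WT and 0.000417 in Neil2KO. It overlaps the named Neil1 transcripts over nearly their whole span on the same strand, and whether it comes from the targeted allele was not tested.

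Genes called in the gene table often lay in loci with unnamed transcripts, 62.5% of 88 called gene and comparison pairs against 23.3% of tested genes. Reads given to unnamed transcripts rather than to the gene were weighed as a technical explanation. Over all 88 pairs the median ratio of locus to table fold change was 0.241 (bootstrap interval from 0.0911, with its upper end at 0.8001), which cannot tell the explanations apart for the set as a whole. In the 55 pairs with unnamed transcripts the ratio was 0.0572 (0.0170 to 0.0905), as division of reads between transcript models predicts, and this split was added after the value had been seen. In the other 33 pairs it was 0.997, but there the locus total holds only named transcripts, so a ratio near 1 follows largely by construction. Changes in these 55 pairs, among them Tmod2, Gng2 and Ndufs7, may therefore be shifts between transcript models rather than in the output of the locus, and a change of isoform is not excluded. Of the called pairs 18.2% (exact 10.8 to 27.8%) lay inside the stretches of lost sites, too few for location to explain the whole set, a bound added after the excess was seen. That share was still 5.58 times that of the tested genes. The excess passed in Neil1KO and DKO (Fisher's exact p = 5.52e-05 and 7.3e-05) and not in Neil2KO (0.0573), where 2 called genes lay inside. In Neil1KO and DKO called genes thus lay inside the stretches more often than tested genes did. The rule asked for an excess in all 3 comparisons, so it gave no verdict on location for the 3 together. All 16 pairs inside were lower. The targeted gene Neil2 is 1 of them in Neil2KO and in DKO. Without Neil1 and Neil2 the share was 5.01 times that of the tested genes (Fisher's exact p = 5.45e-05, 0.312 and 0.000554).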

How the results depend on the processing

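Of the alternative values for counts, levels and relations, 153 stayed within 1.5 times the main count, within the spread of the libraries or on the same side of the threshold, 110 moved further, 1 was stronger and 4 were weaker. A count within that range need not hold the same genes: without WT replicate 1, 65 genes were called in Neil1KO, 23 of them among the main 52. With all 8 libraries in place, named genes kept direction and side of the threshold in 1298 of 1483 alternative values, promoters in 139 of 202 and tiles in 208 of 221. With 1 library left out they did so in 1036 of 1280, 102 of 200 and 229 of 240. Fits of only 2 genotypes called 0, 1, 0, 13 and 6 genes (Neil1KO, Neil2KO, DKO, DKO against Neil1KO, DKO against Neil2KO) and 1, 0 and 7 promoters, with fewer libraries to estimate the spread by construction. Gene sums of FPKM called 106 genes in DKO against Neil1KO (34 higher and 72 lower, against 17 and 11), and 31 higher and 21 lower in Neil1KO. Locus totals called 36 genes in Neil2KO and 22 list tests, and reversed Znrf3 0.26, Gm42256 0.36, Rps2 -0.030 in Neil1KO, Apba2 -0.059, Ndufs7 -0.19, Zranb1 -0.61, Rsl1 0.086 in Neil2KO, Apba2 -0.056, Ndufs7 -0.18, Lacc1 0.066 in DKO, Gm42256 -0.097, Lacc1 0.031 in DKO against Neil1KO, Gng2 -0.22, Zbtb16 0.20 in DKO against Neil2KO and Gng2 -0.089 in the departure from the sum. An estimated correlation and fry (lowest adjusted p 0.104) each left 0 of 14 list tests, as did an estimated correlation over locus totals (0 of 22). The 8 further tests over locus totals were 6 lists that passed in no comparison in the gene table, blood markers in Neil1KO (adjusted p = 0.00936) and astrocyte markers in Neil2KO (0.00985). Without the stretches of lost sites 5 genes were called in DKO, all higher, tiles fell to 68, 20 and 79 (35, 13 and 37 higher) and promoters to 6, 0 and 4. Tiles numbered 593, 269 and 896 at 25 points and adjusted p 0.01, 935, 220 and 1224 without 10 Mb on either side of Neil1 and Neil2, 149, 36 and 313 on the logit scale and 444, 127 and 631 with at least 10 sites. Promoters numbered 7, 0 and 6 at 25 points and adjusted p 0.01, and 0 in Neil2KO and 11 in DKO without those 10 Mb. They numbered 2, 0 and 1 with 500 bp and 3, 0 and 5 on the logit scale. After centring they numbered 36 (10 higher, 26 lower), 28 and 68. Removal of regions and stricter thresholds lower counts by construction, and for the other alternatives the cause was not tested. Over genes called in promoter methylation or expression rho was -0.000141 in Neil1KO (permutation p = 1) and -0.594 in Neil2KO (12 genes, permutation p = 0.0485). Without Neil2 it was -0.491 in Neil2KO (permutation p = 0.132), and in Neil1KO, where neither targeted gene was called, it stayed at -0.000141. Without 1 library, called genes against WT changed their division into higher and lower, from 56 and 18 to 9 and 45 in Neil1KO, 58 and 17 to 7 and 33 in Neil2KO and 45 and 5 to 9 and 46 in DKO. Called genes ranged from 27 to 74, 19 to 75, 5 to 85, 22 to 115, 14 to 91 and 30 to 57 (departures from the sum last), list tests from 10 to 20, tiles from 627 to 1306, 205 to 626 and 926 to 2220, and promoters from 5 to 11, 0 to 1 and 3 to 15. Counts above the main one kept 18 to 25 of the 52, 14 to 19 of the 21 and 10 or 11 of the 15, and the smallest DKO count, 5, kept 3. Level differences changed sign with the library left out and ranged from -0.997 to 1.09, -0.318 to 1.77 and -0.936 to 1.16 points, and rho from -0.0333 to -0.00793, -0.0128 to -0.00197 and -0.0147 to -0.00628. With the replicate number as a block, called genes numbered 22 in Neil1KO, 5 in DKO, 17 in DKO against Neil1KO, 6 in DKO against Neil2KO and 12 for departures from the sum, and promoters 1 in Neil2KO and 14 in DKO. Deviations of same-numbered libraries correlated at -0.0275 to 0.0618, which gives no sign of pairing gene by gene or tile by tile. In each genotype, though, RNA replicate 1 held more genes at 0, more aligned bases and a larger share of unnamed bases than replicate 2. That share was 20.1 and 19.8% in WT, 21.0 and 18.0% in Neil1KO, 21.2 and 18.5% in Neil2KO and 20.1 and 18.6% in DKO. A factor shared by same-numbered RNA libraries is therefore not excluded. Count-based tests, site filters by reads, pooled-read tests and levels weighted by reads were not run, since read counts were not used here and the values could not be turned back into them. Depth limits every methylation level here by an unknown amount.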

Other observations

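In this part the tests of sequence variants and of an overall level difference on all stretches were written before their values were known, and the others were chosen after the result was seen. Some losses were seen in 1 library of a genotype only. On chromosome 14 from 45 to 54 Mb, part of the Neil2KO stretch, 2712 sites lost in Neil2KO replicate 2 stood at a median of 45.5% in replicate 1 (quartiles 36.0 and 55.6%), against 84.5% in WT. On chromosome 5, 2699 sites lost in DKO replicate 1 stood at a median of 44.0% in replicate 2 (35.5 and 53.3%), against 84.4% in WT. Differences over such long stretches argue against the DNA libraries of Neil2KO, or those of DKO, being repeats of the same DNA. Further stretches on chromosome 5 (64 to 65 Mb) and chromosome X (116 to 120 Mb) had 17 and 35 lost sites in DKO replicate 1 and 0 in replicate 2. Near Gm40533 on chromosome 9 the level was low in Neil1KO and not in DKO. The last 1 Mb bin of that stretch with at least 10 lost sites began at 77 Mb in both Neil1KO libraries, at 64 Mb in DKO replicate 1 and at 62 Mb in DKO replicate 2. Mitochondrial transcripts made up between 1.23% (Neil2KO replicate 2) and 4.204% (Neil1KO replicate 1) of aligned bases, with no order by genotype. The first principal component of expression (19.9% of variance) set the Neil1KO libraries (56.9 and 50.9) apart from the other 6 (-32.6 to 3.57).

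The stretches of lost sites were weighed against sequence variants and level differences between libraries, and those around Neil1 and Neil2 also against an effect of the enzymes across the genome. The hypothesis is that they are DNA of another mouse strain in which variants remove CpG sites. Of the 3793 called lower tiles (counted per comparison) inside all stretches 98.6% held a lost site, and with lost sites and their partners left out the median difference went from -26.6 to -3.41 points (bootstrap -3.59 to -3.14), within the bound set for variants. It was -3.30 points in the 3073 tiles of stretches that hold Neil1 or Neil2 and -3.79 in the 720 of the others. A true loss confined to the same single sites would give the same value. Leaving out the lowest sites of tiles called lower also moves the median towards 0 by construction. In simulated tiles not chosen by a call, the median of the sites left was -0.252 with planted lost sites and -24.8 with even lowering. The bootstrap takes tiles as independent, though stretches of DKO and of the single knockouts overlap. After centring, 100% of the tiles were still called lower. Mean levels over shared sites lay between 74.6 and 76.7% in the libraries, so centring could hardly change calls with a median of -26.6 points. An overall level difference of that size is too small to account for these tiles. Within 10 Mb of the targeted genes, a window fixed before the data were seen, tiles were called lower 50.4 times as often as elsewhere (46.3 in Neil1KO, 147.8 in Neil2KO and 33.1 in DKO), where an even effect of the enzymes across the genome predicts under 2. That effect does not account for the stretches around Neil1 and Neil2, which may instead mark DNA inherited with the targeted alleles. The stretches on chromosomes 1, 5, 11 and X in DKO and at 95 to 99 Mb of chromosome 9 in Neil1KO hold neither gene. Linkage to the targeted alleles was not tested for them, and no biological explanation was, so their origin stays open. Without a genome or reads the variants themselves were not seen, and the strain of the targeted cells is not given in the sources used here.

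Outside all stretches 153 tiles were called in Neil1KO. Of these 72.6% (exact 64.8 to 79.5%) had the same sign in DKO against Neil2KO, a comparison that shares no library with the first, so chance values of the WT libraries do not account for the whole set. The other 42 had the opposite sign, and the median of DKO minus Neil2KO was 2.91 points in the higher and -8.83 in the lower tiles, so part of the 153 may be chance. With the stretches left out of the fit 65 tiles were called, of which 53 (81.5%, exact 69.97 to 90.1%) had the same sign, with medians of 16.1 and -17.6 points. The first bounds for this share, 65 and 80%, left the value undecided; they were replaced after it was seen by 50%, the share chance gives when no library is shared. Higher tiles made up 54.3% (46.0 to 62.3%), and variants that remove CpG sites predict that over 90% would be lower. In 80 tiles, among them those at Camk2b and Pik3c3, all 4 Neil1-deficient libraries lay beyond the 4 others. The margin in DKO varied widely among them. DKO minus Neil2KO was 70.5 points in the Camk2b tile at 6006001 but -4.33 at Ldb2 and -1.11 at Reep3. The tiles were chosen by Neil1KO against WT, so part of the 80 may be chance order of the other libraries. The rest could follow from loss of Neil1 or from descent shared by the Neil1-deficient lines. These data cannot tell the 2 apart.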
